A study of Mus musculus with 6 samples.

How the data were processed

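Gene expression was measured on 6 Clariom S mouse arrays, 3 from 3T3-L1 cells treated with the extract (group Tsuru, replicates 1 to 3) and 3 from untreated cells (group control, replicates 1 to 3). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, cells were seeded in medium with 10% serum, induced, changed to insulin medium at day 3 and followed to day 9, and total RNA was extracted with a phenol-based reagent. Per the series design text, cDNA was made from 100 ng of RNA and labelled with the WT PLUS kit, which primes along the whole transcript.

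The deposited value table holds log2 signals, made by the authors with SST-RMA (a signal space transformation followed by robust multi-array averaging) in Transcriptome Analysis Console version 4.0.2, per the series design text, and RMA and the same software are named in the submitters' processing notes. The table has 28846 probe sets. Of these, 6640 are control sets (5222 negative, 1324 positive, 63 ERCC, 23 background, 4 hybridization and 4 poly-A sets) and were left out of the tests, which leaves 22206 transcript clusters. Gene symbols came from the authors' deposited table: 21367 clusters carried 1 symbol, 836 several and 3 none, and no gene was named from a cluster with several. For that reason Srebf1 is not reported. The genome build behind the clusters is not given in the sources used here, so no coordinates are stated. The authors' deposited table also gives p-values and FDR p-values from a one-way ANOVA with empirical Bayes correction, per the series design text, and a signed linear fold change, Tsuru over control, per the file headers. The series design text sets a detection cutoff (DABG) of 0.05, a positive against negative control AUC of at least 0.7, and calls a gene changed at an unadjusted p under 0.05 and a linear fold above 1.1. The group averages in the authors' deposited table lay within 0.01 of the mean of the arrays for 5.26% of clusters in the Tsuru group and 4.83% in the control group, with a median absolute difference of 0.106 and 0.117 on the log2 scale. Its log2 fold changes correlated at 0.86 with those computed here, across clusters, which are not independent replicates, and had the same sign for 82.2%. Why the averages differ from those of the value table was not tested. Fold changes from that table are named as such where printed. A sheet named for signal intensities holds sample descriptions and was not used.

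Array quality was described from the control sets. The AUC of positive over negative control sets was 0.840, 0.828 and 0.829 on the Tsuru arrays and 0.806, 0.825 and 0.833 on the control arrays, each above the authors' limit. Array medians ran from 5.43 to 5.59 on the log2 scale. Control replicate 1 stood apart from the other arrays: its mean correlation with them was 0.9868, against 0.9906 to 0.9918, and it lay at 53.7 on the first principal component, which held 40.5% of the variance, where the others lay between -25.8 and 15.2. No pair of arrays shared more than 10 identical values, so each array was counted as a separate sample. No scan date or batch is given in the sources used here.

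Each cluster was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without a trend), Tsuru minus control over all 6 arrays, with Benjamini-Hochberg adjustment over all clusters and no filter on dim signals. The prior added 5.86 degrees of freedom. Errors of fold changes are moderated standard errors, and errors of group means are standard deviations over 3 arrays. For the gene lists, fixed before the data were examined, each of 21154 genes was represented by its brightest cluster. Of 753 list entries, 713 were matched, 5 of them through an older or newer symbol in a RefSeq gene table. The 32 lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, each adjusted over the lists. Each list's median was also set against 10000 random lists matched on brightness in 20 bins, an alternative chosen after the data were seen. The steps were tested on simulated data: of genes changed in a simulated comparison of Tsuru and control over 22206 clusters, limma recovered 1.49% at a log2 change of 0.5, 59.7% at 1 and 100% at 2, with 8 unchanged genes called. With no shift simulated 0 of 32 lists were called, and 1 was with 1 list shifted by 0.3. Simulated genes varied independently, so this does not test the preset correlation for lists whose members vary together. In the data the estimated correlation reached 0.693, for interferon response.

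The rule for named genes was fixed before the data were examined. It takes the 12 clusters per direction with the largest change among those at an adjusted p under 0.05 with groups that do not overlap, fills empty places with the smallest p past the methods' threshold, adds up to 4 members per list, and always adds 14 adipocyte genes. Predicted genes and olfactory and vomeronasal receptors are passed over. No cluster qualified for the first part, so all 24 came from the second. The alternatives, chosen before the data were examined, were a filter on dim clusters (log2 6 or above in at least 3 arrays), dropping the dimmest 25%, quantile normalization, subtracting array medians, cyclic loess, a variance trend with robust fitting, array weights, a replicate block, leaving out each array in turn, the ordinary ANOVA, the authors' deposited table, 1 cluster per gene, and other list tests. The group left with 2 arrays was assumed to vary like the other.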

Results

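The series measured the transcriptome of 3T3-L1 cells, a mouse fibroblast-like line that turns into fat-storing adipocytes when given an adipogenic hormone mixture. Cells were grown past confluence and induced with IBMX, insulin and dexamethasone, with or without an extract of Tsuruazuki ("Tsuru"), kept in insulin medium from day 3, and collected at day 9. Total RNA was labelled and hybridised to Clariom S mouse arrays, with 3 arrays for the Tsuru group and 3 for the control group. The sample titles describe the controls only as maintained in medium, whereas the treatment protocol describes a control that went through induction without extract. The labels name 1/1000 and 1/100 dilutions of a 100 mg/ml stock and do not say which of them the arrayed cells received. Nothing in the labels states that the 3 samples of a group came from separate cultures, so the p-values below measure only the spread between these samples, which may be technical. The 6 arrays limit the precision: the median standard error of a log2 fold change was 0.195. The comparison asks which transcripts differ between extract-treated and untreated cells at day 9.

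Both groups carried abundant adipocyte transcripts. The preadipocyte marker Dlk1 was bright in both as well, at mean log2 signals of 17.37 with Tsuru and 17.35 without. The fatty acid binding protein gene Fabp4 stood at a log2 signal of 17.80 ± 0.16 (SD, n = 3) with Tsuru and 17.63 ± 0.24 (SD, n = 3) without, and the desaturase gene Scd1 at 19.33 ± 0.06 and 19.19 ± 0.06. Pparg, the nuclear receptor that directs fat cell formation, differed by -0.03 ± 0.19 (SE) on the log2 scale. Higher mean signals with Tsuru were measured for lipid droplet and secreted adipocyte genes: Plin4, which coats lipid droplets, by 0.93 ± 0.16 (SE), Plin1, another droplet coat gene, by 0.90 ± 0.19, and Cfd, which encodes adipsin, by 1.09 ± 0.26. No single gene passed correction for all transcripts. In limma's moderated test with Benjamini-Hochberg adjustment over 22206 transcript clusters (the array's gene-level probe sets), 0 reached an adjusted p under 0.05 and the lowest adjusted p was 0.259. At an unadjusted p under 0.05, 2472 clusters differed, where chance would give 1110.3. All of these also exceeded the 1.1-fold change named in the series' methods, 1277 of them higher and 1195 lower with Tsuru. The same test without the empirical Bayes step gave 0 clusters at an adjusted p under 0.05 as well, and 1948 at an unadjusted one. The 3 Tsuru values lay wholly on one side of the 3 control values for 3734 clusters, or 16.8%, where chance gives 10%. Of the clusters past the methods' threshold, 461 were at least 1.5-fold higher and 626 at least 1.5-fold lower, and 10 and 127 were at least 2-fold. Without control replicate 3, 25 clusters reached an adjusted p under 0.05, 2 of them higher and 23 lower, each at 0.048. The controls left in that fit had the highest readings of the spike-in transcripts dap, thr and phe, but not of lys. These transcripts are added before labelling, so a technical difference goes with the groups in that fit.

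The genes with the smallest p-values in each direction do not pass adjustment, and their values are given as measured. Among the 12 named higher with Tsuru, adjusted p ran from 0.259 to 0.315. Chka, the choline kinase that starts phosphatidylcholine synthesis, had a log2 signal of 6.47 ± 0.19 (SD, n = 3) against 5.11 ± 0.34, a fold of 2.55. Rasl12 followed at 2.03-fold and Micall1 at 2.05-fold, and Rtf1, a transcription elongation factor gene, differed by 1.00 ± 0.19 (SE) on the log2 scale. Plin4 and Trp53inp2, an autophagy gene, combined a bright signal with a narrow spread, at 12.55 ± 0.10 against 11.62 ± 0.07 for Plin4 and 12.30 ± 0.10 against 11.49 ± 0.08 for Trp53inp2. The others were Efcab8, Zfand2b, Cpped1, Txndc16, Borcs7 and Cmc1, with log2 differences from 0.83 for Txndc16 to 0.97 for Zfand2b. Among the 12 named lower, adjusted p ran from 0.259 to 0.341. Tefm, a mitochondrial transcription elongation factor gene, had the widest difference, 6.42 ± 0.51 against 7.98 ± 0.46. Sly, a Y-linked gene present in many copies, differed by -1.40 ± 0.20 (SE) and the meiotic gene Mnd1 by -1.19 ± 0.19. Spata31d1c, Scgb1b19, Tnfrsf25, Cldn34b1, Reps2, Nr6a1 and Cd69 had log2 differences between -0.79 for Cd69 and -1.07 for Cldn34b1. Defa17 and Defa3 carried identical values, -1.06 each, so these 2 clusters count as a single measurement of closely related genes. All 24 had groups that did not overlap, which choosing by the smallest p with 3 arrays per group largely ensures. At least 1 group mean of Sly, Cldn34b1 and Cd69 lay under 4.57, the mean of the array's background sets, so their differences are not exact. The negative control sets averaged more, 5.75 to 6.01 by array. The control mean of Chka lay under 5.75 as well, as did at least 1 group mean of Efcab8, Borcs7, Spata31d1c, Defa17 and Defa3. Clusters of the same gene disagreed for Efcab8, where the others read -0.24 and -0.30, and for Sly, where the others ran from -0.76 to -0.05.

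**Figure D1:**
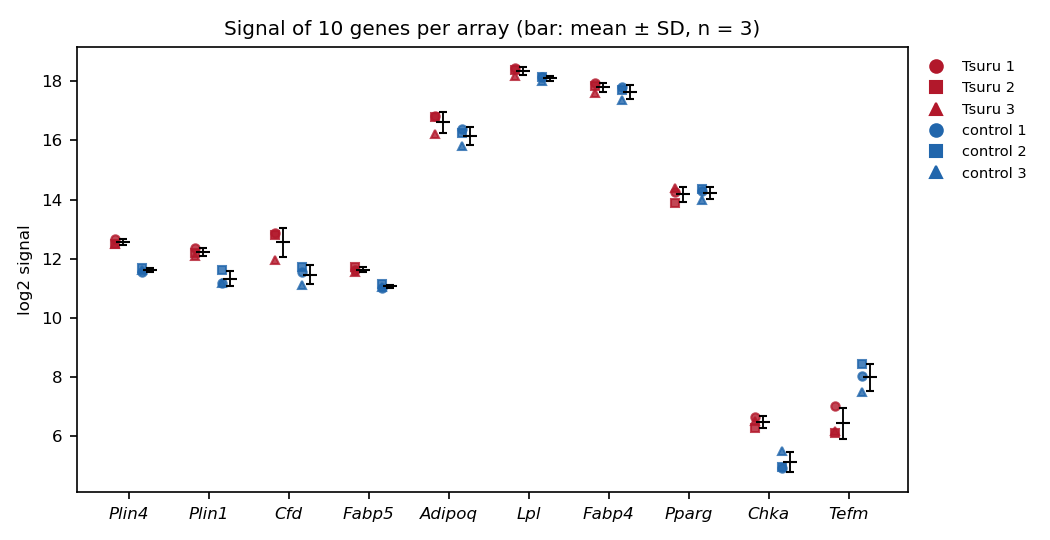
Log2 signal (vertical axis) of 10 genes on each array, with Tsuru arrays in red and control arrays in blue; black bars give the mean ± SD of 3 arrays. The Plin4 values sit at 12.55 ± 0.10 with Tsuru and 11.62 ± 0.07 without, while Pparg differs by -0.03.

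The list of adipocyte and lipid droplet markers shifted higher with Tsuru as a set. Its median log2 fold change was 0.24 over 25 measured members, 20 of them positive (camera with a preset correlation, adjusted p = 0.00028; adjusted p = 0.38 with an estimated correlation). No member passed adjustment over all genes, and 4 did when adjusted over the list alone: Plin1, Plin4, Cfd and Fabp5, the last a fatty acid binding protein gene with a difference of 0.56 ± 0.16 (SE). Adipoq, which encodes adiponectin, differed by 0.47 ± 0.23 and Lpl, the lipoprotein lipase gene, by 0.25 ± 0.16. The triacylglycerol synthesis list shifted by a median of 0.41 over 14 members, 11 of them positive (adjusted p = 0.0018; adjusted p = 0.38 with an estimated correlation). Its members with the smallest p were Agpat9 at 0.56 ± 0.18, the phosphatidate phosphatase genes Lpin1 at 0.49 ± 0.16 and Lpin2 at 0.54 ± 0.19, and Gpd1, which makes the glycerol backbone, at 0.46 ± 0.18. Adipogenic transcription factors had a smaller median, 0.11 over 17 members (adjusted p = 0.045; adjusted p = 0.38 with an estimated correlation), with Ebf1 at 0.44 ± 0.17 and Klf4 at 0.44 ± 0.18. This last call was lost when Tsuru replicate 1, Tsuru replicate 3, control replicate 1 or control replicate 3 was left out, and the median was -0.02 after cyclic loess normalization. Cebpa differed by 0.30 ± 0.22 and Cebpb by 0.09 ± 0.19, and without control replicate 3 by 0.08 and -0.08. Without the same array Adipoq differed by 0.30 and Fabp4 by 0.03. Without control replicate 1 Cebpa differed by 0.51. Fatty acid synthesis genes were not called (median 0.16 over 16 members, adjusted p = 0.25), with Fasn at 0.29 ± 0.18, or 0.14 without Tsuru replicate 3, and Acly at -0.28 ± 0.18, or -0.14 without control replicate 3. Neither were lipolysis genes (0.11 over 14 members, adjusted p = 0.19) or cholesterol synthesis genes (0.09 over 24 members, adjusted p = 0.29). In the lipolysis list Plin1 alone passed when adjusted over the list alone, Lipe stood at 0.33 ± 0.17 and Pnpla2 at -0.04 ± 0.17.

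Genes of mitochondrial energy metabolism made the set shift with the smallest adjusted p. Oxidative phosphorylation genes had a median log2 fold change of 0.35 over 41 members, 37 of them positive and 10 past the methods' threshold (adjusted p = 6.7e-09; adjusted p = 0.22 with an estimated correlation). The complex I subunit genes Ndufb5 and Ndufb9 differed by 0.89 ± 0.20 (SE) and 0.75 ± 0.21, the complex III gene Uqcrfs1 by 0.68 ± 0.17 and the ATP synthase gene Atp5d by 0.69 ± 0.19, while another Atp5d cluster differed by 0.12 ± 0.17. Citrate cycle and branched chain amino acid genes shifted by 0.30 over 33 members, 30 of them positive (adjusted p = 5.7e-05; adjusted p = 0.22 with an estimated correlation). Here Aldh6a1, of valine breakdown, stood at 0.51 ± 0.16 and the pyruvate carboxylase gene Pcx at 0.48 ± 0.17. Glycolysis and hypoxia genes shifted by 0.19 over 24 members, 21 of them positive (adjusted p = 0.0012; adjusted p = 0.38 with an estimated correlation), among them Pgam1 at 0.53 ± 0.18 and Hk1 at 0.60 ± 0.23, or 0.37 without control replicate 1. Fatty acid oxidation genes had a median of 0.20 over 22 members (adjusted p = 0.018; adjusted p = 0.41 with an estimated correlation), with the carnitine carrier gene Slc25a20 at 0.48 ± 0.20 and the regulator Ppara at -0.56 ± 0.23. Slc25a20 was at 0.30 without control replicate 1, and Ppara at -0.34 without Tsuru replicate 1. Their call was lost without Tsuru replicate 1 or control replicate 1, with adjusted p = 0.066 and 0.34. Ribosomal protein genes shifted by 0.24 over 31 members, 30 of them positive (adjusted p = 5.7e-05; adjusted p = 0.38 with an estimated correlation).

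Insulin signalling and glucose transport genes shifted by a median of 0.33 over 22 members, 18 of them positive and 7 past the methods' threshold (adjusted p = 5.7e-05; adjusted p = 0.38 with an estimated correlation). The insulin receptor gene Insr differed by 0.54 ± 0.17 (SE), the kinase gene Pdpk1 by 0.91 ± 0.31 and the glycogen synthase gene Gys1 by 0.55 ± 0.19. Trib3, which encodes an inhibitor of Akt, also had a higher mean at 0.50 ± 0.16, and the glucose transporter gene Slc2a4 stood at -0.03 ± 0.23. AMPK and sirtuin genes had a median of 0.19 over 16 members (adjusted p = 0.037; adjusted p = 0.38 with an estimated correlation), with Sirt6 at 0.63 ± 0.23 and Prkaa2 at 0.53 ± 0.19. The control mean of Prkaa2, 4.07, lay under the mean of the background sets, so its difference is not exact. That call was lost without Tsuru replicate 1 or control replicate 1, with adjusted p = 0.081 and 0.22. Extracellular matrix genes had a median of 0.18 over 36 members, 30 of them positive (adjusted p = 0.0018; adjusted p = 0.43 with an estimated correlation), and lost the call without control replicate 1 (adjusted p = 0.11). The members with the smallest p were the collagen genes Col15a1 at 0.69 ± 0.19 and Col6a3 at 0.47 ± 0.19. NRF2 antioxidant genes had a median of 0.16 over 29 members (adjusted p = 0.018; adjusted p = 0.38 with an estimated correlation), with the haem oxygenase gene Hmox1 at 0.60 ± 0.17. Without Tsuru replicate 1 or control replicate 3 that call was lost, with adjusted p = 0.13 and 0.055. Unfolded protein and integrated stress genes had a median of 0.14 over 30 members (adjusted p = 0.016; adjusted p = 0.38 with an estimated correlation), with the chaperone gene Hyou1 at 0.50 ± 0.16 and the serine synthesis gene Phgdh at -0.33 ± 0.17. Their call was lost without Tsuru replicate 1 or control replicate 3, with adjusted p = 0.081 and 0.066.

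**Figure D2:**
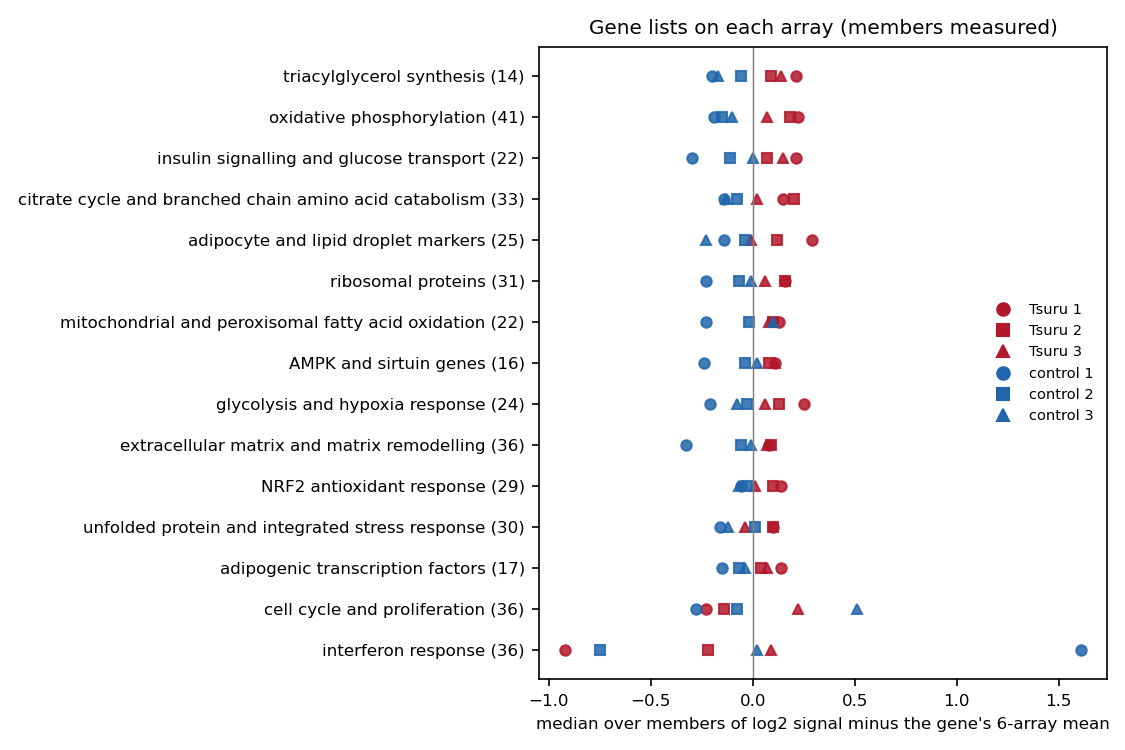
For the 14 called lists and the cell cycle list, the median over members of the log2 signal minus each gene's mean over the 6 arrays (horizontal axis, log2), 1 point per array, with Tsuru arrays in red and control arrays in blue. For oxidative phosphorylation the Tsuru arrays lie between 0.07 and 0.22 and the control arrays between -0.19 and -0.10, while for interferon response control replicate 1 alone lies at 1.61.

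Interferon response genes made the single list called lower, with a median of -0.61 over 36 members, 35 of them negative (adjusted p = 5.7e-05; adjusted p = 0.54 with an estimated correlation). None of its members passed the methods' threshold. The list's median deviation on control replicate 1 was 1.61, against -0.75 and 0.02 on the other controls and between -0.92 and 0.09 on the Tsuru arrays. Ifi44, an interferon-induced gene, read 12.27 on control replicate 1 and 7.92 and 9.47 on the other controls. Its difference of -1.78 became -0.59 without control replicate 1 and -2.76 without control replicate 2. Without control replicate 1 the list's median was 0.05 and the call was lost (adjusted p = 0.88). Cell cycle genes were not called (median -0.15 over 36 members, adjusted p = 0.073; adjusted p = 0.76 with an estimated correlation), with Kif11 at -0.62 ± 0.26 (SE) and Aurka at -0.57 ± 0.26, or -0.32 without Tsuru replicate 1. Without control replicate 1 that list had a median of -0.29 and was called lower (adjusted p = 0.00022), and without control replicate 3 the median was 0.08. That list was also called lower after quantile normalization (-0.26, adjusted p = 0.0026) and cyclic loess (-0.26, adjusted p = 0.0025). Calls also came with the filter at log2 6, without the dimmest 25%, and with array medians subtracted, array weights, the replicate block or ranks. The same held without Tsuru replicate 3 or control replicate 2. It stayed uncalled without Tsuru replicate 1, Tsuru replicate 2 or control replicate 3, and with a variance trend. Nor was it called with fry (adjusted p = 0.75), with the mean over a gene's clusters, or without genes in more than 1 list. Its median lay at percentile 0 of brightness-matched lists, with an estimated correlation of 0.487.

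Markers of the progenitor state and of other cell types were not called. Preadipocyte and progenitor markers had a median of 0.02 over 16 members (adjusted p = 0.67), with Dlk1, the preadipocyte marker, at 0.02 ± 0.19 (SE). Thermogenic and beige markers had a median of -0.06 over 18 members (adjusted p = 0.72), with Ucp1 under the mean of the background sets in both groups, at 3.49 ± 0.08 (SD, n = 3) against 3.62 ± 0.05. Ppargc1b differed by 0.53 ± 0.16 (SE) and Tmem26 by -0.49 ± 0.21, or -0.28 without control replicate 2, and these were the members past the methods' threshold, 1 in each direction. Macrophage and leukocyte markers had a median of -0.08 over 18 members (adjusted p = 0.29) at a mean log2 signal of 4.58, with Lyz2 at -1.29 ± 0.52 and Mrc1 at -1.15 ± 0.43. Without control replicate 1 Lyz2 was at -0.73 and Mrc1 at -0.76. Endothelial markers had a median of -0.12 over 11 members (adjusted p = 0.19), and Cdh5 passed when adjusted over the list alone, with both group means, 3.33 and 3.92, under the mean of the background sets. The medians were 0.03 for epithelial markers (adjusted p = 0.75), 0.01 for skeletal muscle markers (adjusted p = 0.89) and 0.00 for osteoblast and chondrocyte markers (adjusted p = 0.67). In the epithelial and muscle lists the test leaned lower while the median was positive. The remaining lists were not called either: aryl hydrocarbon receptor targets at 0.18 (adjusted p = 0.18), contractile genes at 0.13 (0.12), the Wnt pathway at 0.09 (0.19), p53 targets at 0.11 (0.25), heat shock genes and metallothioneins at 0.05 (0.25), inflammatory genes at 0.04 (0.61) and glucocorticoid response at 0.01 (0.83). In all, 14 of 32 lists were called with the preset correlation, 0 with an estimated correlation and 0 with fry, where the lowest adjusted p was 0.072. At an unadjusted p under 0.05, 4 lists passed with an estimated correlation and 12 with fry. The estimated correlation was 0.015 for the citrate cycle list and 0.019 for NRF2 genes, near the preset 0.01, and 0.693 for interferon response. Correlation among members is thus not the only reason that calls were lost with the estimate. With an estimated correlation, camera takes its degrees of freedom from the arrays, which are few. With a preset one it takes them from the number of genes, so the same test statistic gives a smaller p. After quantile normalization or cyclic loess, 9 of the 14 calls were left: the lists of adipogenic transcription factors, AMPK and sirtuin genes, fatty acid oxidation, NRF2 and the unfolded protein response lost theirs.

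Fold changes depended on brightness. Clusters with a mean log2 signal from 4 to 6 had a median log2 fold change of -0.075, and those from 8 to 10 a median of 0.143. Of the clusters lower with Tsuru past the methods' threshold, 74.0% had a mean log2 signal under 6, against 23.0% of those higher. Olfactory and vomeronasal receptor genes, whose median signal was 4.06, made up 17.5% of the lower clusters and 6.35% of all clusters (odds ratio 3.50, two-sided Fisher's exact p = 5.55e-43 across clusters, which are not independent). Of 1410 receptor clusters, 209 were lower and 11 higher past the threshold. With only the 10057 clusters at a log2 signal of 6 or above in at least 3 arrays, 1326 passed the methods' threshold, 1004 higher and 322 lower. Subtracting each array's median left 2026 higher and 766 lower, a share of 72.6% higher in place of 51.7%.

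**Figure D3:**
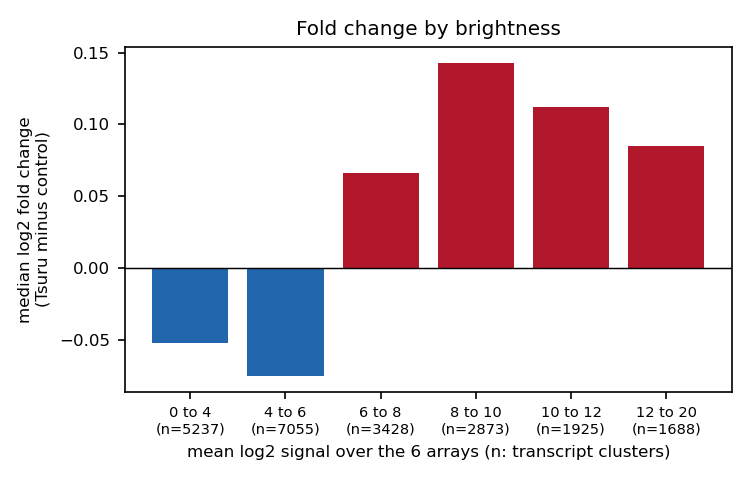
Median log2 fold change, Tsuru minus control (vertical axis), of transcript clusters grouped by their mean log2 signal over the 6 arrays (horizontal axis); bars start at 0. The median is -0.075 for signals from 4 to 6 and 0.143 for signals from 8 to 10.

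The authors' deposited table gives 2641 clusters past both of the methods' thresholds, 1333 higher and 1308 lower, and 0 with an FDR under 0.05, the lowest being 0.1319. Of these, 1968 also passed here in the same direction and 0 in the opposite one. Both sets of calls rest on the same 6 arrays, so their overlap is not independent evidence. The authors' deposited table lists Chka at 2.81-fold, Plin4 at 1.83-fold, Cfd at 2.11-fold and Adipoq at 1.67-fold. Of the 157 genes taken by the naming rule, 154 had the same direction in the authors' deposited table as here. The other 3 were Slc2a4 at 1.37-fold, Cebpb at -1.04 and Dlk1 at -1.07, where a negative sign means lower with Tsuru. For 39 of the 157 the log2 fold change there was reversed or over 1.5 times apart from the value here, among them Ifi44 at -1.93-fold, Mrc1 at -3.65, Slc25a20 at 1.16 and Apaf1 at 1.01 in the authors' deposited table. Their filtered table holds 2033 clusters, 1267 higher and 766 lower, and leaves out 609 that passed both thresholds in the authors' deposited table, 193 of them olfactory or vomeronasal receptors.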

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

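The combination of cyclic loess with control replicate 1 left out, the brightness-matched lists, and the authors' fold changes of single genes, were chosen after the data were seen. The count at an adjusted p under 0.05 was 0 under every alternative that kept all 6 arrays, and 0 to 25 with 1 array left out, alone or with the 1.5-fold condition. The 25 came without control replicate 3, where 16 were predicted genes or clusters with several symbols. The methods' threshold gave 1326 clusters with the filter at log2 6, which tests fewer clusters, and 1659 to 3616 with 1 array left out. Against 14 called lists, 0 were called with an estimated correlation or with fry. The filter at log2 6 gave 9 of the 28 lists tested there, 8 of the 14 and cell cycle. Cyclic loess without control replicate 1 gave 8, 7 of the 14 and cell cycle. Leaving out 1 array gave 9 to 15, new calls included. Of all 32 lists, 9 lay outside the central 95% of brightness-matched lists, among them cell cycle, which was not among the 14 called. The cause of these differences was not tested beyond the fewer clusters or arrays. Whether the replicate numbers pair the samples is not settled. The deviations of same-numbered arrays correlated at 0.00, 0.01 and 0.19, and those of the other pairs at -0.13 to 0.12. The value for replicate 3, 0.19, was the highest, so a pairing there is not excluded. With the replicate block 2775 clusters passed the methods' threshold, 0 passed an adjusted p under 0.05, and 14 lists were called, with adipogenic transcription factors lost and cell cycle gained. The lowest adjusted p in limma was 0.127 with the block and 0.259 without it. Of 2458 gene values under the alternatives, 2436 kept their direction, and 2 (Chka and Sly, both without control replicate 3) passed adjustment. Most of these genes were named for a small p on the same 6 arrays. A gene whose groups do not overlap cannot reverse when 1 array is left out, so much of this agreement was fixed in advance.

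The 22 reversed gene values belonged to Pparg, Slc2a4, Dlk1, Pnpla2 and Cebpb, whose log2 fold changes lay between -0.04 and 0.09, and to Apaf1, at 0.63. Apaf1 read 6.24 on control replicate 1 and 7.95 and 8.05 on the other controls. Its difference was 0.05 without control replicate 1, so the 0.63 rests on that array. The cause of the other reversals was not tested. With array medians subtracted Pnpla2 was 0.04, Pparg 0.05 and Slc2a4 0.05, and with array weights Slc2a4 was 0.02. Cebpb was -0.05 after quantile normalization and -0.04 after cyclic loess, where Dlk1 was -0.02. After cyclic loess without control replicate 1, Apaf1 was -0.03 (0.05 to 0.95 with 1 array left out), Dlk1 -0.12 and Slc2a4 0.13. In the authors' deposited table Slc2a4 was 0.45, Cebpb -0.06 and Dlk1 -0.10 on the log2 scale. With 1 array left out, Pparg ran from -0.15 to 0.11, Slc2a4 from -0.20 to 0.19, Dlk1 from -0.10 to 0.16, Pnpla2 from -0.14 to 0.04 and Cebpb from -0.08 to 0.18.

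Of 636 list values, 38 had the test turn direction; the cause was not tested, and medians are given. Glucocorticoid response was -0.10 after quantile normalization, -0.10 after cyclic loess, 0.04 with the filter at log2 6, 0.01 without the dimmest 25% and -0.03 without shared genes. Thermogenic markers were -0.01, -0.03, 0.16 and 0.09 under the first 4 of these. Epithelial markers were 0.08 and 0.09, and skeletal muscle markers 0.06 and 0.07, after quantile normalization and cyclic loess. The filter at log2 6 gave 0.10 for cholesterol synthesis, 0.17 for inflammatory genes and 0.02 for progenitor markers, and dropping the dimmest 25% gave 0.14 for endothelial markers. After cyclic loess without control replicate 1, cholesterol synthesis was -0.08, glucocorticoid response -0.10, interferon response 0.02, epithelial 0.03, macrophage 0.04, muscle -0.05, p53 targets -0.04 and progenitor markers 0. With 1 array left out, interferon response ran from -1.05 to 0.05, cell cycle from -0.29 to 0.08, cholesterol synthesis from -0.02 to 0.31, glucocorticoid response from -0.10 to 0.15, thermogenic markers from -0.13 to -0.03, epithelial from -0.10 to 0.01, muscle from -0.09 to 0.07, p53 targets from 0.01 to 0.16, progenitor markers from 0.01 to 0.08, macrophage markers from -0.10 to 0.02, endothelial markers from -0.18 to -0.07 and inflammatory genes from 0.02 to 0.07. Signal over background limits the dim lists, whose members lie near the level of the receptor genes.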

Other observations

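The symbol families, the brightness-matched lists, the tests of receptor and dim clusters, the spike-in values and the weighing of explanations were chosen after the results were seen, whereas the gene lists, cyclic loess, the median subtraction and the leaving out of arrays were chosen before. Histone genes, which package newly made DNA, stood out in a screen of 128 families of gene symbols, 20 of which were called with the preset correlation and none with an estimated one. Their median log2 fold change was -0.38 over 59 members, 52 of them negative (camera, adjusted p = 6.4e-07; adjusted p = 0.58 with an estimated correlation), at a bright mean log2 signal of 10.88. The median was -0.46 after cyclic loess, -0.30 with array medians subtracted, and between -0.67 and -0.17 with 1 array left out. By array, the histone genes lay at -0.39, -0.51 and 0.35 on the Tsuru arrays and -0.02, 0.18 and 0.40 on the controls, so Tsuru replicate 3 lay with the controls. The cell cycle list had its highest values on the same 2 arrays, 0.22 on Tsuru replicate 3 and 0.51 on control replicate 3.

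Mitochondrial ribosomal protein genes had a median of 0.17 over 75 members, 55 of them positive, with 10 higher and 1 lower past the methods' threshold (adjusted p = 0.0018; adjusted p = 0.49 with an estimated correlation). Brightness-matched lists had a median of 0.09, and the family lay at percentile 97.93 of them, with Mrpl genes alone at 91.31 and Mrps genes alone at 88.56. After cyclic loess the median was 0.12, with 28 members negative. The poly-A spike-in controls, added to the RNA before labelling, differed between arrays: the dap transcript read 8.33 and 8.32 on control replicates 1 and 2, 6.84 on control replicate 3 and 6.88 to 7.31 on the Tsuru arrays. The thr transcript read 6.86, 6.78 and 5.59 on the controls and 5.57 to 6.06 with Tsuru, whereas phe was higher on each control (5.25, 5.17 and 4.84) than on the Tsuru arrays (4.45 to 4.59), and lys differed by 0.04 in the mean. The hybridization controls were lower on the Tsuru arrays by means of -0.27 to -0.36. For bioB, bioC and cre the groups did not overlap, so a technical difference went with the groups. Whether it adds to the gene shifts was not tested.

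The higher metabolic lists may reflect the brightness trend, since bright genes had higher fold changes in general. For 7 of the 13 lists called higher, the call was kept after cyclic loess and the median lay above the central 95% of brightness-matched lists. These were adipocyte markers, triacylglycerol synthesis, oxidative phosphorylation, citrate cycle, glycolysis, insulin signalling and ribosomal proteins. By these checks the trend is not the whole of their shift. Both checks treat members of a list as nearly independent, while the estimated correlations ran from 0.015 for the citrate cycle to 0.242 for adipocyte markers. None of the 7 was called with an estimated correlation, so a shift beyond the variation between arrays is not shown. That test has few degrees of freedom here, so the lack of a call does not show that there is no shift. The trend still goes with part of their shift, as cyclic loess lowered the median from 0.24 to 0.15 for adipocyte markers, 0.41 to 0.29 for triacylglycerol synthesis, 0.35 to 0.23 for oxidative phosphorylation, 0.30 to 0.16 for the citrate cycle, 0.19 to 0.12 for glycolysis, 0.33 to 0.22 for insulin signalling and 0.24 to 0.13 for ribosomal proteins. The same 7 kept the call with each array left out, all with the preset correlation. For the other 6 the trend remains open, as each lost the call or lay inside that range. A larger share of converted adipocytes cannot be told apart from a change within cells, since the progenitor list had a median of 0.02 with members going both ways. An effect of the extract is untested beyond this comparison: of the 10 splits of the 6 arrays the real one called 14 lists and the highest other 11, and 10 splits are too few for a share under 0.05. For clusters past the methods' threshold the real split gave 2472 and the highest other 1775 (1 of 10 splits as large), and for an adjusted p under 0.05 all 10 splits gave 0.

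The lower interferon list is consistent with a signal in control replicate 1 alone, since its median was 0.05 without that array. Why that sample differed was not tested.

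The dim receptor genes lower with Tsuru had a median of -0.20. The tables argue against the brightness trend as the whole cause, since after cyclic loess the median was -0.13 and its percentile among 10000 brightness-matched lists was 0. They also argue against control replicate 1 alone, without which the median was -0.13. The receptor signal, 4.06 in the median, lay under the mean of the background sets, 4.57, so these differences are not exact. The matched lists treat genes as independent, and with an estimated correlation olfactory receptors were not called (camera, adjusted p = 0.49). Genomic DNA in the RNA of some controls may contribute: dim clusters shared by several gene symbols, which extra DNA copies would raise, had a median of -0.14 against -0.05 for matched dim clusters with 1 symbol, a percentile of 0. Any gain in cross-hybridization would do the same, so that test is not specific. By array, the shared clusters deviated by 0.15, 0.06 and -0.02 on control replicates 1 to 3 and by -0.10, -0.04 and -0.10 on the Tsuru arrays. Control replicate 3 thus lay near Tsuru replicate 2 and did not show the rise. An effect of the extract stays open and untested.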
